A study of Homo sapiens with 37 samples.

How the data were processed

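Human placental tissue was profiled with the NanoString GeoMx Digital Spatial Profiler, an instrument that releases barcoded RNA probes from chosen regions of a tissue section with light and counts the barcodes by sequencing. The study concerned placenta accreta spectrum, in which the placenta adheres abnormally to the uterine wall. Per the labels' protocols, control, invasion-site and opposite-site tissue shared slides, with 3 matched pairs on 3 slides, and regions of interest were chosen on the scanned slides. The marker or morphology behind that choice is not given in the sources used here. The labels list 12 control regions, 12 regions from the invasion site, 12 from the opposite, non-invaded site of accreta placentas, and 1 no-template control. Control region 5 and the no-template control were not analysed here, which left 11 control, 12 opposite and 12 invasion regions. Region numbers within a group were given in accession order and pair nothing.

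The deposited table holds log2 values for 11163 genes, with 1 column per region and no negative probes. Back on the linear scale each column summed to 1000000, and 100% of the values in every column were whole multiples of that column's step within a tolerance of 0.01. The deposited values were therefore read as log2 CPM (counts scaled to a column total of 1000000 over the listed genes), with no pseudocount. This reading comes from the values. The protocol in the labels names the Cancer Transcriptome Atlas panel of 1825 genes, fewer than the table lists, and no source used here settles which panel was read. The counting tool, probe filter, genome build and any outlier removal by the authors are not given in the sources used here. Every value is relative to the region's total, so a gene or background signal that takes a larger share lowers all others.

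The recovered totals ran from 725958 to 3410981 counts per region. The lowest count of any gene in any region was 16, and the median gene had 53 to 228 counts. Counting error for the median gene was thus 6.62% to 13.7% of its count. Counting accounted for a median of 36.3% of the variance between regions of a gene in control, 44.0% at the opposite and 67.9% at the invasion site. A count also includes non-specific probe signal, which the table gives no negative probes to measure. As a substitute, 283 genes of families not expected in placenta (221 olfactory receptors, 42 hair keratin-associated proteins, 12 bitter taste receptors, 3 vomeronasal receptors and 5 lens crystallins) served as a background level and are called silent families here. That list was written after the table was opened but before these genes' values were examined. Genes with a group mean above the 95th percentile of these families in any group numbered 1920 of 11143, and 9223 did not reach it.

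From 11163 genes, 20 were left out because their level could describe a person, which left 11143. Some of these were added to the exclusions, on the same principle, once the gene names were known. Chi-square comparisons of recovered counts found no pair of regions within a group that agreed within sampling noise.

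The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on the deposited log2 values, with 1 mean per group, all 35 regions in the fit and 32 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg over 11143 genes, two-sided, with a threshold of 0.05. The design fixed before the data were examined foresaw whole-number counts or linear normalized values of 36 regions. Because the table holds log2 values with no zeros, no pseudocount was added and 35 regions were fitted. Comparisons were invasion against opposite, each site against control, and the mean of both sites against control. The labels tie no region to a donor or slide, and there were more regions than donors. Some regions therefore share a donor, p-values over regions are too small, and no donor or slide term could be fitted.

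Before the data were examined, 33 gene lists were fixed: 16 of cell type markers and 17 of gene groups. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. Adjusted p-values for lists are Benjamini-Hochberg over the 33 lists within a comparison. Camera asks whether a list moved relative to all other genes. Single genes were also adjusted over each list alone. Named genes follow a rule fixed at the same time: the 10 highest and 10 lowest log2 fold changes among genes passing the test in each of the first 3 comparisons, and up to 4 members with the smallest p from each list described. Members of multigene families such as HLA, ribosomal proteins, HSPA1B and immunoglobulins are uncertain between copies.

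Because the median of all genes against control moved by more than 0.1 on the log2 scale, changes against control are given relative to that median, with the adjusted p of the test on the deposited values. Alternatives were upper quartile scaling, quantile normalization, TMM factors on the linear values, a Mann-Whitney test, only genes with a mean above the median gene, other pseudocounts, only the groups compared, no variance trend, array weights, each of 35 regions left out, and a test against a log2 fold change of 0.5. Chosen after seeing the data were median centring, a pseudocount of 1, voom on recovered counts, a total without placental lactogen genes, removal of regions with fewer than 1000000 counts, and covariates for the silent-family and syncytiotrophoblast levels.

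The test was tried on simulated data for 11143 genes with 200 planted changes. At a log2 change of 0.5 it recovered 96% of planted genes for invasion against opposite, 89% for invasion against control and 92% for opposite against control. At a log2 change of 1 it recovered 100% in each, and false calls numbered 8, 8 and 11. The simulated noise was independent between genes and between regions, with no donor or slide effect. These rates therefore do not cover the shared donors and co-varying genes of the real data. Gene positions are from GENCODE 29 (GRCh38), matched by symbol for 10882 of 11143 genes. The reference may differ from the authors' build. Figures and joins used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.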

Results

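Expression of 11143 genes was measured in 35 tissue regions of human placenta: 11 from control placentas, 12 from the invasion site of placenta accreta and 12 from the opposite, non-invaded site. The design text sets the invasion site against the opposite site, and accreta placentas against controls. Total counts averaged 1828080 (SD 588286, n = 12) at the invasion site, 1911483 (SD 810381, n = 12) at the opposite site and 1960746 (SD 486371, n = 11) in control regions. The spread of log2 CPM over genes was 0.541 at the invasion site, 0.594 at the opposite site and 0.682 in controls. The families not expected in placenta had a median level of 6.15 log2 CPM at the invasion site, 5.89 at the opposite site and 5.96 in controls. CSH2, which encodes placental lactogen and is uncertain between copies, took 1.2% ± 0.58 (SD, n = 12) of counts at the invasion site, 2.08% ± 2.36 (SD, n = 12) at the opposite site and 4.72% ± 3.26 (SD, n = 11) in controls. Means below are followed by SD, with n = 12 for each accreta site and n = 11 for control.

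The first comparison asked what distinguishes the invasion site from the non-invaded site of accreta placentas. PAGE4, a marker of villous cytotrophoblast (chromosome X, 49829260 to 49833973), fell to 230 ± 66.5 CPM from 529 ± 275 CPM (log2 fold change −1.07, SE 0.21, adjusted p = 0.0013). DLK1, an imprinted Notch-family ligand of fetal stroma (chromosome 14, 100725705 to 100738224), fell to 232 ± 25.6 CPM from 508 ± 184 CPM (−1.06, SE 0.14, adjusted p = 1.066e-05). IGF2, an imprinted fetal growth factor, fell to 1027 ± 307 CPM from 2082 ± 658 CPM (SE 0.19 on the log2 scale, adjusted p = 6.545e-04). Each of these 3 was below the mean of the opposite site in 12 of 12 invasion regions. The other genes among the 10 lowest were SPP1 (osteopontin), the matricellular gene TINAGL1, the interferon-inducible IFI6, RPL13, the imprinted PHLDA2 and PEG10, and SUPT7L, with log2 fold changes from −0.87 to −0.74.

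Cytotrophoblast and villous stroma markers, ribosomal genes and TGF-beta genes lay lower at the invasion site, while no fall was called for syncytiotrophoblast markers. Of 18 villous cytotrophoblast markers, 0 rose and 8 fell, and adjusted over the list alone also 8 fell (median log2 fold change −0.38, camera adjusted p = 8.823e-12). Among them were SPINT1, a protease inhibitor of epithelia (−0.71, SE 0.12), and BCAM, a laminin receptor (−0.70, SE 0.10). Of 12 pericyte and villous stroma markers, 8 fell, and adjusted over the list alone 8 fell and 1 rose (median −0.30, camera adjusted p = 8.027e-08). These included the pericyte receptor NOTCH3 (−0.55, SE 0.10), the collagen gene COL6A3 (−0.64, SE 0.15) and MCAM, an adhesion molecule of perivascular cells (−0.56, SE 0.16). MCAM did not pass with a Mann-Whitney test (adjusted p = 0.0545) or without opposite region 12 (−0.46, adjusted p = 0.0507). Of 37 ribosomal protein genes, 32 fell, and 33 adjusted over the list alone (median −0.51, camera adjusted p = 4.334e-43), for example RPS16 (−0.63, SE 0.09) and RPL11 (−0.56, SE 0.08). Of 22 genes of mesenchymal transition and TGF-beta signalling, 5 fell, and 5 adjusted over the list alone (median −0.12, camera adjusted p = 2.857e-05). That count depended on scaling, with 11 lower after quantile normalization, 9 with upper quartile scaling, 7 with TMM factors and 9 with median centring. They included the filament gene VIM (−0.70, SE 0.15), BMP7 (−0.44, SE 0.09), TGFB3 (−0.38, SE 0.11) and ID3 (−0.36, SE 0.09). These 4 lists also passed with an estimated correlation (adjusted p = 0.0456 each). Against control, 13 of 18 cytotrophoblast markers were higher at the opposite site (median 0.45, 0.26 relative to all genes) and 6 at the invasion site (median 0.059, −0.18 relative). Of 37 ribosomal genes 35 were higher at the opposite site and 8 at the invasion site, so both lists lay nearer control at the invasion site. Camera on the deposited values did not call the cytotrophoblast list at the opposite site against control (adjusted p = 0.0555, 0.769 with an estimated correlation). It did with quantile normalization (9.929e-04) and TMM factors (0.0113). After median centring no member of either list was higher than control there, and 2 cytotrophoblast markers and 1 ribosomal gene were lower, while with quantile normalization 4 cytotrophoblast and 27 ribosomal members were higher. Among 27 syncytiotrophoblast markers 0 passed, also adjusted over the list alone (median −0.02, camera adjusted p = 0.20). Their list mean varied widely, at 8.34 ± 0.39 log2 CPM at the invasion and 8.32 ± 0.91 at the opposite site. A fall as large as that of the cytotrophoblast list is thus not excluded for them. Above the background level lay 16 of 18 cytotrophoblast, 6 of 12 pericyte and villous stroma, 37 of 37 ribosomal, 9 of 22 TGF-beta and 23 of 27 syncytiotrophoblast genes. Because regions share donors, these p-values are too small.

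**Figure D1:**
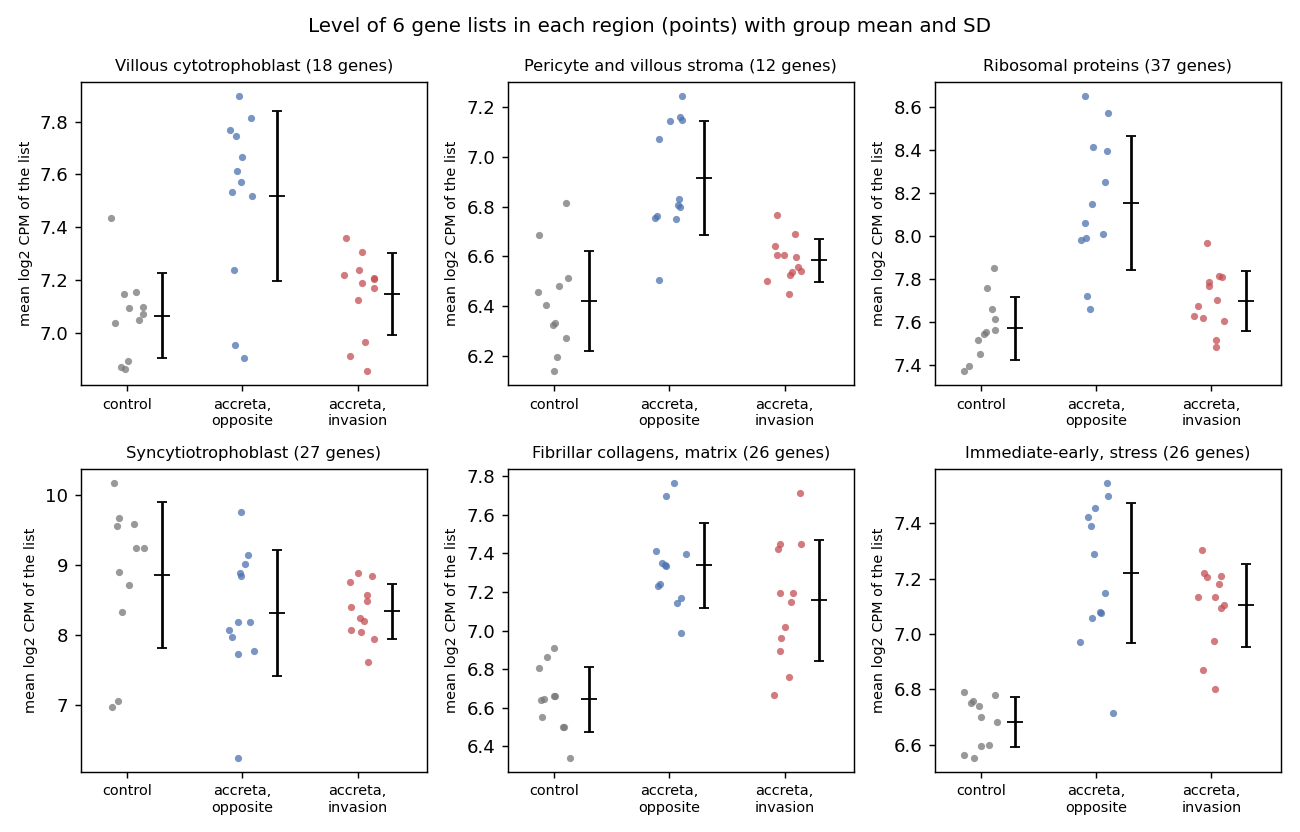
Mean log2 CPM of the members of selected gene lists, per region (points) and as group mean with SD (bars), for 11 control, 12 opposite and 12 invasion regions. Villous cytotrophoblast markers averaged 7.06 in control, 7.52 in opposite and 7.15 in invasion regions, and ribosomal protein genes 7.57, 8.16 and 7.70.

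Some members of matrix, vessel, antigen presentation and macrophage lists fell at the invasion site, and camera called these lists lower only at its preset correlation. Of 16 basement membrane genes 4 fell and 1 rose, and adjusted over the list alone 10 fell and 2 rose (median −0.23, camera adjusted p = 8.785e-07, adjusted p = 0.169 with an estimated correlation). The laminin chains LAMA5 (−0.64, SE 0.11) and LAMC1 (−0.52, SE 0.11) were among them. Of 26 fibrillar collagen and matrix genes 5 fell, and 6 adjusted over the list alone (median −0.18, camera adjusted p = 1.891e-05, adjusted p = 0.226 with an estimated correlation). Of 14 class I antigen presentation genes 6 fell, and 6 adjusted over the list alone (median −0.12, camera adjusted p = 4.266e-05, adjusted p = 0.105 with an estimated correlation), including B2M (−0.64, SE 0.15) and HLA-E (−0.63, SE 0.11). Of 22 blood vessel endothelial markers 4 fell, and 6 adjusted over the list alone (median −0.10, camera adjusted p = 9.112e-05, adjusted p = 0.105 with an estimated correlation), including the junction genes CDH5 (−0.55, SE 0.12) and PECAM1 (−0.55, SE 0.14). Of 20 macrophage and Hofbauer cell markers 4 fell, and adjusted over the list alone 7 fell and 1 rose (median −0.10, camera adjusted p = 2.678e-04, adjusted p = 0.226 with an estimated correlation), with the complement gene C1QC, which did not lie above the silent families, at −0.48 (SE 0.11). Counts of lower members were larger in other settings. With quantile normalization, upper quartile scaling, TMM factors and median centring they were 9, 11, 10 and 11 for basement membrane, and 6, 8, 8 and 10 for fibrillar matrix. For endothelium they were 8, 6, 6 and 7, and for macrophages 7, 8, 8 and 8. Above the background level lay 8 of 16 basement membrane, 16 of 26 fibrillar matrix, 7 of 14 class I, 7 of 22 endothelial and 5 of 20 macrophage genes. All of these p-values over regions are too small.

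Lymphoid marker lists lay slightly higher at the invasion site. Of 16 T cell markers 3 rose, and 4 adjusted over the list alone (median 0.20, camera adjusted p = 0.0153, adjusted p = 0.412 with an estimated correlation), including the kinase LCK (0.26, SE 0.07). Of 15 B and plasma cell markers 4 rose, also adjusted over the list alone (median 0.19, camera adjusted p = 0.037, adjusted p = 0.226 with an estimated correlation), including IGHG3 (0.25, SE 0.06), which did not pass after median centring (0.17, adjusted p = 0.05). The call of this list was lost with quantile normalization (adjusted p = 0.0638). Of 7 dendritic cell markers 1 rose, and 6 adjusted over the list alone (median 0.22, camera adjusted p = 0.033, adjusted p = 0.372 with an estimated correlation). Of these markers, 0 of 16, 2 of 15 and 0 of 7 lay above the background level of families not expected in placenta, and neither LCK nor IGHG3 did. Those silent families themselves had a median log2 fold change of 0.22 between the sites. Here too p-values over regions are too small.

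The 10 highest genes at the invasion site were TRIM36, NUTM2G, WIPF3, CPNE5, ADAMTS3, LAD1, ZNF727, DRD3, HSD3B7 and SLC23A3, with log2 fold changes from 0.64 down to 0.47. NUTM2G averaged 177 ± 31.2 CPM against 116 ± 21.9 CPM (0.62, SE 0.13, adjusted p = 0.0016, too small as above). In control regions all 10 followed the level of a block of 54 genes described below. CPNE5, LAD1, ZNF727 and SLC23A3 are members of that block, and each was set against the other 53 (r of 0.948 or more for the 10). With each region centred on its median, TRIM36 (0.64 to 0.55, adjusted p = 0.0553), CPNE5 (0.51 to 0.43, 0.0774), LAD1 (0.50 to 0.42, 0.0795), ZNF727 (0.48 to 0.40, 0.0803), HSD3B7 (0.48 to 0.39, 0.0713) and SLC23A3 (0.47 to 0.38, 0.0633) did not pass. Each of these 6 also lost its call when any of several regions was left out (7 to 18 of 35), for example opposite region 4 (adjusted p from 0.0675 to 0.102). TRIM36 and DRD3 did not lie above the silent families. With the level of the silent families as a covariate, chosen after seeing the data, these 10 genes did not pass, with 5.72% (SLC23A3) to 55.8% (NUTM2G) of their change left. The calls of SPP1 (−0.87 to −0.58, SE 0.22), PHLDA2 (−0.76 to −0.52, SE 0.21), PECAM1 (−0.55 to −0.35, SE 0.16), LCK (0.26 to 0.14, SE 0.073) and IGHG3 (0.25 to 0.17, SE 0.070) also ended, with 54.5% to 68.1% left.

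In total 1506 of 11143 genes differed between the accreta sites in limma, 936 higher and 570 lower, and the median of all genes was 0.09. The balance turned with scaling: 412 higher and 1034 lower with upper quartile scaling, 808 and 1258 with quantile normalization, 461 and 983 with TMM factors, and 286 and 1149 with median centring. Among called genes above the background level, 114 were higher and 348 lower. That level was exceeded by 1825 genes at the opposite site and 1054 at the invasion site, so the filter itself leans towards lower genes. Tested against a log2 fold change of 0.5, limma called 0 genes (18 at an unadjusted p under 0.05). The count was 2884 without opposite region 1, 683 without opposite region 4, 887 without opposite region 7, 926 without opposite region 12 and 951 without invasion region 11. P-values over regions are too small, because regions share donors.

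**Figure D2:**
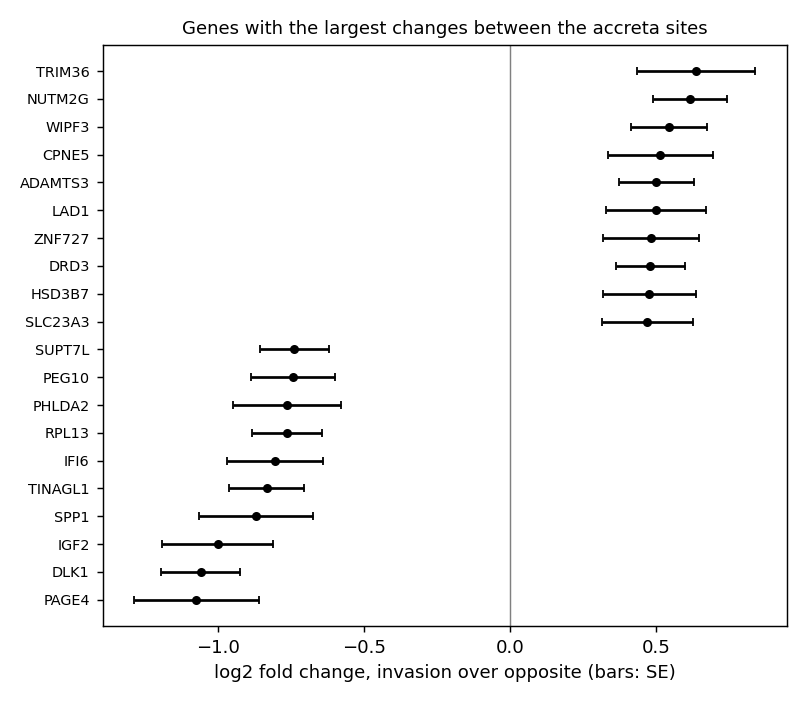
Log2 fold change of the 10 highest and 10 lowest genes passing the test, invasion over opposite site, with bars of 1 SE (12 regions per site). The lowest is PAGE4 at −1.07 and the highest TRIM36 at 0.64.

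The second comparison asked how the invasion site differs from control placenta. The median of all genes lay 0.24 higher on the log2 scale at the invasion site, and changes below are relative to it. PRG2, the eosinophil major basic protein gene that extravillous trophoblast also expresses (chromosome 11, 57386794 to 57390657), rose to 714 ± 563 CPM from 189 ± 234 CPM (relative log2 fold change 1.79, SE 0.59, adjusted p = 0.0028, higher in 10 of 12 regions). FOS, an immediate-early transcription factor gene (chromosome 14, 75278774 to 75282230), rose to 1101 ± 479 CPM from 344 ± 141 CPM (1.37, SE 0.27, adjusted p = 6.509e-06, higher in 12 of 12 regions). AOC1, the diamine oxidase of extravillous trophoblast, rose by 1.24 (SE 0.31), COL1A1, a fibrillar collagen chain, by 1.05 (SE 0.26), and the fibronectin gene FN1 by 1.01 (SE 0.40). DDX4, HSPA1B, CCN2, IL1RL1 and THBS1 completed the 10 highest, from 0.99 to 0.80, and DDX4 did not pass after median centring (1.03, adjusted p = 0.0649) or with TMM factors (0.99, adjusted p = 0.0813). KISS1, the kisspeptin gene of syncytiotrophoblast (chromosome 1, 204190341 to 204196486), fell to 303 ± 176 CPM from 1091 ± 881 CPM (−1.68, SE 0.48, adjusted p = 0.0083). KISS1 did not pass with quantile normalization (−1.04, adjusted p = 0.0588). With the silent-family covariate KISS1 went from −1.44 to −0.070 (SE 0.32, adjusted p = 0.854) on the deposited scale. FN1 (1.25 to 0.80, SE 0.42, adjusted p = 0.0897) and DDX4 (1.22 to 0.94, SE 0.50, adjusted p = 0.0952) lost their calls with most of the change left. KISS1 is also one of the 54 genes at least 2-fold lower at both sites described below, but did not vary with the other 53 in control regions (r of −0.756). P-values over regions are too small in this comparison.

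Members of matrix, stress, trophoblast, decidual and muscle lists rose at the invasion site, while camera on the deposited values did not separate these lists from other genes. Of all 11143 genes 6653 were called higher there, and of 283 silent-family genes 159. The extravillous trophoblast and smooth muscle counts below lie near those shares. Other lists rose as widely: 8 of 9 NK cell, 5 of 5 lymphatic, 11 of 14 class I and 12 of 16 basement membrane genes were higher. With quantile normalization camera called fibrillar matrix (adjusted p = 4.253e-04), immediate-early (0.002), extravillous trophoblast (0.0459), smooth muscle (0.0473), basement membrane (0.037), class I (0.002) and ribosomal (4.482e-07) lists higher. With TMM factors it called fibrillar matrix (0.0357). At an estimated correlation, on the deposited values, each of these 7 lists had an adjusted p = 0.95. Of 26 fibrillar collagen and matrix genes 21 rose and 1 fell, also adjusted over the list alone, and 15 rose and 1 fell after median centring (camera adjusted p = 0.413). The proteoglycan gene DCN was 0.48 higher (SE 0.11) and COL14A1 0.39 (SE 0.11). Of 26 immediate-early and stress genes 20 rose and 1 fell, also adjusted over the list alone, and 8 rose and 3 fell after centring (camera adjusted p = 0.531). NR4A1, a nuclear receptor induced early after stimulation, was 0.80 higher (SE 0.16), KLF6 was 0.51 higher (SE 0.10) and FOSL1 was 1.26 lower (relative value −1.26, SE 0.16). FOSL1 is one of 54 co-varying genes described below (r of 0.978), for which a technical source stays open. Of 21 extravillous trophoblast markers 11 rose and 0 fell, also adjusted over the list alone, and 8 rose after centring (camera adjusted p = 0.883). The matrix protease gene MMP2 was among them (0.34, SE 0.08). Of 14 decidual stroma markers 11 rose, also adjusted over the list alone, and 7 rose and 2 fell after centring (camera adjusted p = 0.413), with the decidual transcription factor gene HAND2 at 0.48 (SE 0.10) and IGFBP1 at 0.33 (SE 0.10). Of these 14 decidual markers, 2 lay above the background level. Of 14 smooth muscle markers 9 rose, also adjusted over the list alone, and 5 after centring (camera adjusted p = 0.768), with the muscle filament gene DES at 0.59 (SE 0.17). Above the background level lay 16 of 26 fibrillar, 18 of 26 immediate-early, 15 of 21 extravillous and 9 of 14 smooth muscle genes, but not COL14A1, HAND2, IGFBP1 or DES. These p-values over regions are too small.

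On the deposited values, syncytiotrophoblast markers were the only list of 33 that camera called at the invasion site against control. Of 27 members 6 fell and 2 rose, and adjusted over the list alone 5 fell and 2 rose (median −0.50, −0.74 relative to all genes, camera adjusted p = 1.940e-06). The call was lost with an estimated correlation (adjusted p = 0.95), with quantile normalization (adjusted p = 0.345) and with TMM factors (adjusted p = 0.121). The hormone gene LEP (−0.91, SE 0.16) and ERVW-1, the syncytin that fuses trophoblast (−0.91, SE 0.17), were among those that fell, and ERVW-1 did not pass with the silent-family covariate (−0.68 to −0.30, SE 0.15, on the deposited scale). For all lists of this comparison p-values over regions are too small.

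The other 9 of the 10 lowest genes at the invasion site were PITX1, MYBPC2, ZNF727, GAL3ST4, FAIM2, ADAM32, NETO1, BANK1 and RSPO1, with relative log2 fold changes from −1.67 to −1.44. MYBPC2, a muscle myosin-binding protein gene (chromosome 19, 50432903 to 50466321), averaged 100.4 ± 17.9 CPM against 284 ± 112 CPM in control, and NETO1 did not lie above the silent families. All 10, KISS1 included, were among 54 genes at least 2-fold lower at both accreta sites, which across control regions had a median pairwise r of 0.969. Of the 54, 53 had r above 0.8 to the level of the others, KISS1 being the exception. Level-matched sets had a median of 0.0549 and a highest value of 0.249. Genes with r above 0.8 to this block numbered 2454 of 11143, and they made up 988 of the 1122 genes lower at the invasion site (88.1%). Outside the 54 the count was 935 of 1068.

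Against control, 7775 genes passed in limma at the invasion site, 6653 higher and 1122 lower. The split was 4937 higher and 1661 lower with upper quartile scaling, 2622 and 2085 with quantile normalization, 1901 and 2573 with TMM factors, and 2667 and 2285 with median centring. Of the called genes 1070 lay above the background level, 756 higher and 314 lower. That level was exceeded by 1054 genes at the invasion site and 615 in control, so the filter itself leans towards higher genes. P-values over regions are too small, because regions share donors.

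The third comparison set the opposite, non-invaded site against control. The median of all genes lay 0.19 higher on the log2 scale at the opposite site, and changes are relative to it. PRG2 rose to 1360 ± 1799 CPM from 189 ± 234 CPM (relative log2 fold change 2.35, SE 0.59, adjusted p = 3.632e-04, higher in 11 of 12 regions). FN1 (chromosome 2, 215360440 to 215436172) rose to 913 ± 858 CPM from 192 ± 114 CPM (1.75, SE 0.40, adjusted p = 8.138e-05, higher in 11 of 12 regions). SPP1 (chromosome 4, 87975650 to 87983426) rose to 340 ± 191 CPM from 93.1 ± 29.2 CPM (1.57, SE 0.20, adjusted p = 3.325e-09, higher in 12 of 12 regions). HSPA1B, COL1A1, AOC1, NR4A1, FOS, IGF2 and IGFBP3 followed, from 1.57 to 1.24, and shared donors make these p-values too small.

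Most members of ribosomal, matrix and antigen presentation lists rose at the opposite site, where 5667 of all 11143 genes were called higher. Camera called 5 such lists at its preset correlation, but with an estimated correlation each had an adjusted p = 0.634. Of 37 ribosomal protein genes 35 rose, also adjusted over the list alone, and 32 after median centring (camera adjusted p = 3.125e-07), for example RPLP0 (0.72, SE 0.11). Of 16 basement membrane genes 16 rose, also adjusted over the list alone, and 15 after centring (camera adjusted p = 5.839e-04), including NID1 (0.74, SE 0.12), COL15A1 (0.56, SE 0.09) and LAMA5 (0.73, SE 0.11). Of 14 class I antigen presentation genes 14 rose, also adjusted over the list alone, and 12 after centring (camera adjusted p = 0.0013), including B2M (0.95, SE 0.15) and the peptide-loading gene TAPBP (0.59, SE 0.08). Of 26 fibrillar collagen and matrix genes 21 rose and 1 fell, also adjusted over the list alone, and 18 rose and 2 fell after centring (camera adjusted p = 0.0017), including SPARC (1.04, SE 0.17) and the fibrillin gene FBN1 (0.76, SE 0.12). Of 22 genes of mesenchymal transition and TGF-beta signalling 20 rose and 2 fell, also adjusted over the list alone, and 15 rose and 2 fell after centring (camera adjusted p = 0.0166), including CCN2 (1.07, SE 0.15) and TGFB3 (0.63, SE 0.11). Above the background level lay 37 of 37 ribosomal, 8 of 16 basement membrane, 7 of 14 class I, 16 of 26 fibrillar matrix and 9 of 22 TGF-beta genes. For these lists too, p-values over regions are too small.

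Hypoxia, stress, perivascular and macrophage lists were called higher at the preset correlation with larger p-values. With an estimated correlation these calls were lost (adjusted p = 0.634 for hypoxia, stress and perivascular lists and 0.705 for macrophages). Of 26 hypoxia and glycolysis genes 19 rose, also adjusted over the list alone (camera adjusted p = 0.034), including the glycolytic enzyme genes ALDOA (0.50, SE 0.10) and ENO1 (0.44, SE 0.09). Of 26 immediate-early and stress genes 19 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.034), including KLF6 (0.76, SE 0.10). Of 12 pericyte and villous stroma markers 9 rose, also adjusted over the list alone (camera adjusted p = 0.0448), including NOTCH3 (0.58, SE 0.11) and EGFL6 (0.48, SE 0.10). Of 20 macrophage markers 16 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0448), including MS4A4A (0.32, SE 0.07). ENO1 and MS4A4A did not lie above the silent families. With TMM factors 12 hypoxia, 14 stress, 8 perivascular and 10 macrophage genes rose. Syncytiotrophoblast markers were lower, with 6 of 27 falling and 1 rising, and adjusted over the list alone 4 falling and 1 rising (median −0.54, −0.72 relative to all genes, camera adjusted p = 5.839e-04). That call was lost with an estimated correlation (adjusted p = 0.705), quantile normalization (0.0653) and TMM factors (0.0933). INHBA, an inhibin subunit gene, was at −1.25 (SE 0.24) and LEP at −1.09 (SE 0.16). Of 7 dendritic cell markers 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0397, adjusted p = 0.634 with an estimated correlation). Above the background level lay 10 of 26 hypoxia, 18 of 26 stress, 6 of 12 perivascular and 5 of 20 macrophage genes. Of syncytiotrophoblast markers 23 of 27 did, and of dendritic cell markers 0 of 7. In each of these tests p-values over regions are too small.

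The 10 lowest genes at the opposite site were PITX1, ZNF727, MYBPC2, GAL3ST4, FAIM2, ADAM32, ANK1, LAD1, GLT1D1 and CPNE5. PITX1, a homeobox gene of hindlimb and pituitary development (chromosome 5, 135027735 to 135034813), averaged 246 ± 119 CPM against 1109 ± 561 CPM in control (relative log2 fold change −2.29, SE 0.36, adjusted p = 5.452e-06). All 10 are members of the block of 54 genes. Of the 1619 genes lower at this site, 1402 (86.6%) had r above 0.8 to the block in control regions, and 1349 of 1565 outside the 54.

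At the opposite site 7286 genes passed in limma, 5667 higher and 1619 lower than control. The split was 5412 higher and 1881 lower with upper quartile scaling, 2949 and 2241 with quantile normalization, 2354 and 2791 with TMM factors, and 3510 and 2383 with median centring. Of the called genes 1316 lay above the background level, 965 higher and 351 lower. That level was exceeded by 1825 genes at the opposite site and 615 in control, so the filter itself leans towards higher genes. P-values over regions are too small, because regions share donors.

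In the contrast of both accreta sites with control, basement membrane genes (15 of 16 higher, camera adjusted p = 0.0246), class I antigen presentation genes (14 of 14 higher, 0.0246), fibrillar matrix genes (21 of 26 higher and 1 lower, 0.0319) and ribosomal protein genes (32 of 37 higher, 0.0443) were called higher. With an estimated correlation these 4 lists and the syncytiotrophoblast list each had an adjusted p = 0.929. After median centring 17 of 37 ribosomal genes were higher, with TMM factors 10 of 37, and the list call was lost with upper quartile scaling (adjusted p = 0.0881). With TMM factors 8 of 14 class I and 12 of 16 basement membrane genes were higher. Of 26 fibrillar matrix genes 19 were then higher and 2 lower. Syncytiotrophoblast markers fell (9 of 27 lower and 2 higher, camera adjusted p = 2.800e-05), a call lost with quantile normalization (0.0973) and TMM factors (0.0592). Adjusted over the list alone the counts were the same, except 7 lower syncytiotrophoblast markers. In limma 8284 genes passed, 6821 higher and 1463 lower, with a median of all genes of 0.22. The split was 5847 higher and 1845 lower with upper quartile scaling, 3208 and 2282 with quantile normalization, 2447 and 2858 with TMM factors, and 3596 and 2477 with median centring. Again p-values over regions are too small.

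Both sites were compared with the same control regions, which alone makes their fold changes alike. PRG2, FN1, COL1A1, AOC1, HSPA1B and FOS were among the 10 highest at both sites. Across genes, which are not independent replicates, the fold changes correlated at 0.882, while simulated unchanged groups against these controls gave a median of 0.614 and a range of 0.0367 to 0.953. The covariance was 0.0953 against a simulated mean of 0.0051 (SD 0.0049), a difference of 0.0902. With the controls split into 6 and 5 regions the correlation had a median of 0.820. Of all genes 89.1% had the same sign, against a simulated median of 71.8% and a highest of 91.1%. Genes higher at both sites numbered 4981, against 3384 for independent lists and at most 1425 in the simulations (median 0). Genes lower at both sites numbered 1057, against 163 for independent lists and at most 2250 in the simulations (median 0). The simulations drew single regions, with no donor or slide effect shared by the accreta sites. They also held no shift of total or background common to both sites. An excess over them thus cannot tell a change of accreta from such shared effects. On the deposited scale 2 genes were called in opposite directions, DLK1, lower at the invasion site and higher at the opposite site, and DEFB103A, an epithelial defensin gene chosen after its values were seen, with the reverse. Relative to the median of all genes only DLK1 kept opposite signs (−0.62 and 0.49), while DEFB103A was lower at both sites (−0.086 and −0.42).

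**Figure D3:**
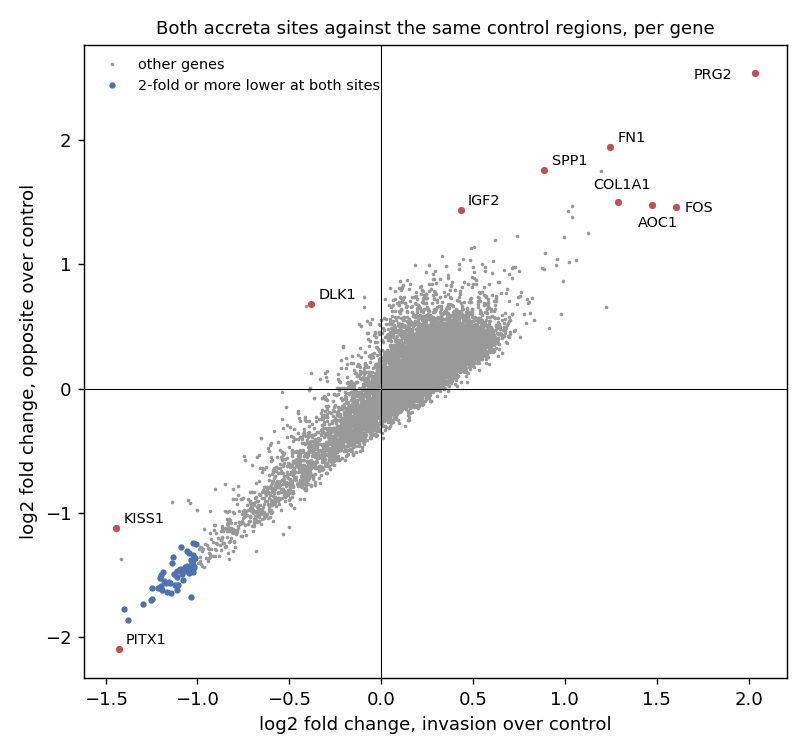
Log2 fold change against the shared 11 control regions for each of 11143 genes, invasion site on the horizontal axis and opposite site on the vertical axis, on the deposited scale. Blue points are genes at least 2-fold lower at both sites, and red points are named genes. PRG2 lies highest on both axes, at 2.03 and 2.54.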

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

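Chosen after the result was seen were the level-matched test, the spread of cell type lists, and the upper quartile and lactogen tests. So were the silent-family values without co-varying members, and the GC and syncytiotrophoblast tests at the opposite site. Expected outcomes were written first for depth on the placental lists, all silent families at the invasion site and other groupings. The same holds for probe background of the co-varying genes, and for their GC and syncytiotrophoblast tests at the invasion site. The removal of shallow regions and the covariates, which some of these tests use, were settings chosen after seeing the data.

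On the deposited scale, effects against control differed between the accreta sites for 2 genes called in opposite directions. DLK1 was −0.38 at the invasion site (adjusted p = 0.0148) and 0.68 at the opposite site (adjusted p = 6.962e-05), a difference of −1.06 (adjusted p = 1.066e-05, lower in 12 of 12 invasion regions). DEFB103A, chosen after its values were seen and uncertain between gene copies, was 0.15 (adjusted p = 0.0472) and −0.23 (adjusted p = 0.0042), a difference of 0.38 (adjusted p = 3.492e-04), at a level within that of the silent families. Relative to the median of all genes DLK1 was −0.62 and 0.49, still opposite, and DEFB103A was −0.086 and −0.42, lower at both sites. After median centring DEFB103A did not pass at the invasion site (adjusted p = 0.656). For 4 lists the difference between sites also passed with an estimated correlation: villous cytotrophoblast (median −0.38), pericyte and villous stroma (−0.30), mesenchymal transition and TGF-beta (−0.12) and ribosomal protein genes (−0.51). Regions share donors, so these p-values are too small.

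The first pattern is the lower cytotrophoblast, villous stroma and ribosomal lists at the invasion site. Against control the cytotrophoblast list had 13 of 18 members higher at the opposite site and 6 at the invasion site, and the ribosomal list 35 and 8 of 37 (35 and 27 with quantile normalization). On these counts the pattern is also a rise at the opposite site, with the invasion site nearer control. Of all 11143 genes 5667 were higher at the opposite site and 6653 at the invasion site. Relative to all genes the cytotrophoblast median was 0.26 and −0.18. Camera on the deposited values did not call this list against control at the opposite site (adjusted p = 0.0555, 0.769 with an estimated correlation). A general loss of signal over background was tested by level, and 3 of the 3 lists lay below the 2.5th percentile of 10000 level-matched lists. TGF-beta (0.01), basement membrane (0), fibrillar matrix (0.01), endothelial (0.02) and class I (0.83) lists lay below it too. Syncytiotrophoblast markers lay at percentile 69.2. This test alone thus cannot exclude a general fall of expressed genes. Silent families rose by 0.22 between the sites, against 0.09 for all genes, as a larger share of background would give. Among 1303 expressed genes outside the co-varying block cytotrophoblast markers lay at percentile 0.03 and ribosomal genes at 0, with too few villous stroma members to test. This argues against a general loss as the whole cause for the cytotrophoblast and ribosomal lists. Matched expressed genes also fell, with medians of −0.13 and −0.16 against −0.41 and −0.51 for the lists, so a general part of the size stays open. Matched genes were drawn singly, while list members vary together (estimated correlation 0.34 and 0.77), so the percentiles are too extreme. The 2 regions of lowest depth, opposite region 11 and invasion region 5, are argued against as the whole cause. Without them 42 of 48 lower members (87.5%) still passed. They come from both sites, so their removal does not test depth in the other regions. With the silent-family level as covariate 30 of 48 passed and their median moved from −0.52 to −0.41, so background may contribute to part of the size. That covariate is not background alone, since 113 of 283 silent genes followed the co-varying block in controls (r above 0.8). The medians of the 14 cell type lists outside this pattern spread over 0.325 on the log2 scale, between the values expected with and without different tissue, and the highest of them, dendritic cells, is at the background level. Region choice and a change within cells of accreta were thus not separated by these data.

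The second pattern is the excess of higher genes in accreta against control. Values are relative to a total, and at the invasion site the higher share of 85.6% became 74.8% with upper quartile scaling, 55.7% with quantile normalization and 42.5% with TMM factors. The excess thus turned with TMM factors. Quantile normalization and TMM factors balance the groups by design, so scaling cannot be told apart from a real shift. Without placental lactogen genes in the total the median shift was 0.15 in place of 0.24, which leaves their part open as well. At the invasion site silent families moved by 0.24, as far as all genes, so non-specific background taking a larger share stays open there. Without the members that follow the co-varying block they moved by 0.35, against 0.29 for all genes outside the block. Of 11143 genes 9223 did not lie above these families, and a change of total moves both alike. The match over all silent families thus cannot tell background from scaling or placental lactogen reads. At the opposite site the 283 silent genes moved by 0.043, but the 113 that follow the co-varying block moved by −0.38 and pull this value down. The other 170 moved by 0.152, against 0.24 for all genes outside the block. That is short of the whole shift but above the 0.05 that would argue against background, so a part of it stays open there. A biological change stays open at both sites.

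The third pattern is the 54 genes lower at both accreta sites. Their median transcript GC was 57.3%, against 48.6% for all genes. A smooth trend of fold change on transcript GC is argued against as the cause. After its removal 93.4% of their median change was left at the invasion site and 94.1% at the opposite site. GC of the probe targets was not tested and stays open. Loss of syncytiotrophoblast is likewise argued against, since 110% and 109% were left with that level as covariate. Probe background that differs between hybridisations met its written expectation, with a median pairwise r of 0.969 within control regions (KISS1 alone did not vary with the others). Any gradient shared by regions, of tissue or of technique, would give such an r, so it cannot tell these apart. Of the 54 genes 3 were in silent families where 1.37 were expected, though that share is within chance (one-sided binomial p = 0.158). The mean level of the 54 was 7.997 ± 0.55 log2 CPM (SD, n = 11) in control, 6.49 ± 0.30 (SD, n = 12) at the opposite and 6.87 ± 0.30 (SD, n = 12) at the invasion site, and 49 of 54 lay above the silent families in control. Slides held several groups per the protocol but regions are not tied to slides, so a technical source and a biological one stay open.

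For each comparison 100 groupings of the same regions were counted, the real one included, treating regions as independent. Only 1 of 100, the real one, gave a count as large in each comparison. For invasion against opposite the real count was 1506 and the highest other 22. It was 7775 against 3860 for invasion and control, 7286 against 3124 for opposite and control, and 8284 against 0 for both sites and control. The real counts thus lay beyond those of regrouped single regions. Regions share donors, so regrouping single regions cannot tell a difference between groups from one between donors.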

How the results depend on the processing

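The lactogen total, median centring, voom, the pseudocount of 1, the removal of shallow regions and both covariates were chosen after seeing the data. No paired analysis was possible because region numbers were given in accession order and no label ties a region to a donor or slide. Invasion against opposite (1506 genes) was the least stable count: 2261 with a Mann-Whitney test, 2845 with only the groups compared, 4991 with array weights, 0 when tested against a log2 fold change of 0.5 (18 at an unadjusted p under 0.05), 712 with the silent-family covariate and 3559 with the syncytiotrophoblast covariate. With 1 region left out it ran from 683 to 2884. Left-out ranges were 7597 to 7913 for invasion against control, 6857 to 7454 for opposite against control and 8010 to 8400 for both sites. For invasion against control (7775) the count was 4707 with quantile normalization, 4474 with TMM factors, 4952 with median centring, 3501 among the upper genes by mean and 15 against a log2 fold change of 0.5. For opposite against control (7286) the last 2 settings gave 3539 and 343. For both sites (8284) they gave 3939 and 198, quantile normalization 5490 and TMM factors 5305. The upper-gene counts are lower partly because fewer genes were tested, and the cause of the other moves was not tested.

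Called lists between sites numbered 20, against 4 with an estimated correlation and 12 with fry, which asks another question. At invasion against control they numbered 1, against 0, 27 and 7 with quantile normalization. At opposite against control they numbered 11, against 0 and 28. For both sites they numbered 5, against 0, 29, 10 with quantile normalization and 8 with TMM factors. The correlation of 0.882 between sites was 0.820 with split controls. Of 156 named gene results, 111 did not pass against a log2 fold change of 0.5, 23 with the silent-family covariate, 12 with median centring, 11 with some region left out, 10 with TMM factors and 7 with upper quartile scaling. PRL and PGR, higher between sites by 0.24 and 0.23, reversed to −0.027 and −0.0055 with the silent-family covariate. All other named results kept their direction in the settings run. The planned count-based size factors and count tool were not run, since the plan tied them to a table of whole-number counts and this one holds log2 values. Voom on the recovered counts was run in their place. Dropping the low-value filter changes nothing because none was applied. Depth limits small changes, since counting made up a median of 67.9% of a gene's variance at the invasion site, and background limits genes near the silent families, 9223 of 11143, PRL and PGR among them.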

Other observations

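Signalling and stress lists between the accreta sites moved in parts. Of 20 integrin and adhesion genes 5 fell and 1 rose at the invasion site, also adjusted over the list alone (camera adjusted p = 0.0065, adjusted p = 0.226 with an estimated correlation). Of 20 Wnt genes 4 fell, among them CTNNB1, which encodes beta-catenin (−0.65, SE 0.10), and adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.0187, 0.416 with an estimated correlation). Of 21 interferon response genes 5 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0421, 0.412 with an estimated correlation). Of 26 hypoxia and glycolysis genes 4 fell, also adjusted over the list alone, ALDOA among them (−0.56, SE 0.10; camera adjusted p = 0.0157, 0.226 with an estimated correlation). Of 26 immediate-early and stress genes 2 fell, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 7.421e-04, 0.226 with an estimated correlation), with the flow-responsive KLF2 at −0.31 (SE 0.07). Of 30 angiogenic genes 3 fell and 1 rose, and adjusted over the list alone 5 fell and 4 rose (camera adjusted p = 0.021, 0.226 with an estimated correlation), the lymphangiogenic VEGFD rising by 0.40 (SE 0.12) but by 0.050 (SE 0.11) with the silent-family covariate. VEGFD did not pass without opposite region 4 (0.37, adjusted p = 0.0574) and did not lie above the silent families. Of 25 housekeeping genes 4 fell, also adjusted over the list alone (camera adjusted p = 0.0134, 0.260 with an estimated correlation). Of 21 extravillous trophoblast markers 1 fell, also adjusted over the list alone (camera adjusted p = 0.037, 0.420 with an estimated correlation). That member was MCAM, which is also in the pericyte and villous stroma list and lost its call in some settings, as given above. Lower members with quantile normalization, upper quartile scaling, TMM factors and median centring numbered 8, 6, 6 and 6 for integrins, 7, 6, 6 and 6 for angiogenic genes and 1, 4, 4 and 5 for immediate-early genes. With quantile normalization the call was lost for extravillous trophoblast (0.735), immediate-early (0.235), housekeeping (0.215), interferon (0.0976) and hypoxia (0.0749) lists. It was also lost with upper quartile scaling for extravillous trophoblast (0.179) and interferon (0.0623), and with TMM factors (0.156 and 0.0689). Above the background level lay 5 of 20 integrin, 2 of 20 Wnt, 5 of 21 interferon and 10 of 26 hypoxia genes. Of immediate-early genes 18 of 26 did, of angiogenic genes 8 of 30, of housekeeping genes 11 of 25 and of extravillous markers 15 of 21. P-values over regions are too small throughout, because regions share donors.

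The remaining lists were not called between the sites, with the members passing over all genes given here. They were decidual stroma (2 of 14 higher, camera adjusted p = 0.279), gland epithelium (1 of 6 lower, 0.133), lymphatic endothelium (1 of 5 lower, 0.685), smooth muscle (0 of 14, 0.231) and matrix proteases and inhibitors (1 higher and 2 lower of 28, 0.139). Uterine NK cells had 1 of 9 higher (0.614), neutrophils and mast cells 2 of 8 higher (0.374), erythroid genes 1 of 7 higher (0.395) and class II antigen presentation 0 of 6 (0.750). Inflammatory cytokines had 4 of 21 higher (0.133), complement and coagulation 1 higher and 1 lower of 21 (0.119), and cell cycle 0 of 20 (0.133). These counts depended on scaling: higher cytokines numbered 4 with quantile normalization, 0 with upper quartile scaling, 1 with TMM factors and 0 with median centring. Lower cell cycle genes numbered 6, 3, 3 and 5, and lower complement genes 3, 2, 2 and 2. Higher decidual markers numbered 3, 0, 1 and 0. Adjusted over the list alone, 3 decidual, 1 gland, 2 higher and 2 lower lymphatic, 0 smooth muscle, 1 higher and 2 lower protease, 1 NK, 3 neutrophil and mast, 2 erythroid, 0 class II, 5 cytokine, 1 lower complement and 0 cell cycle genes passed. Shared donors make these p-values too small.

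Against control, inflammatory genes moved in opposite directions within their list. Of 21 cytokine and chemokine genes 14 rose and 4 fell at the invasion site, also adjusted over the list alone, and 13 rose and 6 fell after median centring (camera adjusted p = 0.768). TNFAIP3, an inhibitor of NF-kappa-B signalling, was 0.41 higher relative to all genes (SE 0.08). At the opposite site the neutrophil-attracting CXCL2 (relative −1.13, SE 0.12) and the chemokine CCL3 (−1.22, SE 0.13) were lower, and both had r above 0.8 to the co-varying genes. Of this list 1 of 21 lay above the background of silent families, and TNFAIP3 and CXCL2 did not. P-values over regions are again too small.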
